A study of Mus musculus with 6 samples.

How the data were processed

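The samples were primary hippocampal neurons from wild-type mice, kept in Neurobasal medium with B27 and GlutaMAX. At culture day 10 the neurons received apolipoprotein E (apoE) particles of either astrocytic or microglial origin at 6 µg/mL for 24 h, and total RNA was sequenced on a DNBSEQ platform. Each treatment had 3 samples, 6 in all, and each sample was assigned to its group from the treatment recorded for it. Neurons without particles were not analysed here, so each direction below is microglial against astrocytic apoE and none is relative to untreated cells. The labels do not say that the 3 samples of a group came from separate cultures or animals. The p-values therefore measure the spread between these samples as deposited, which may be technical.

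The tables deposited by the authors hold a single log2-scale value per gene symbol and sample, for 47593 symbols, with no header. The submitters' processing notes name FastQC, HISAT2, featureCounts and DESeq2 with the mouse build GRCm38, without their roles. Tool versions, the annotation release and the strand setting of the counting are not given in the sources used here. The values themselves show that these log2 values are neither raw counts nor logarithms of plain normalized counts. The same 21031 symbols stood at exactly 0 in all 6 libraries, no symbol stood at 0 in only some of them, and the lowest values lay near -1.965 in each library. Weakly expressed genes were drawn towards their own mean over the libraries. These are the properties of a regularized logarithm, and the transformation is inferred from the values, since no label states it. A regularized logarithm shrinks the fold change of weakly expressed genes, so fold changes given here understate the change of such genes. The spread is shrunk as well: the median SD within a group was 0.0216 at values of 4 to 6, 0.0336 at 6 to 8 and 0.0362 at 8 to 10, where counting alone would give 0.255, 0.121 and 0.0617 if 2^value were a count. At values of 10 to 12 it was 0.0326, still under the 0.0346 of counting. Only at 12 or more, with 805 tested genes, did it exceed counting (0.0312 against 0.0181). SDs and SEs of genes at values under 12, most of those tested, are those of the transformed values and understate the spread between samples. The true depth of each library is unknown. The sum of 2^value was 18060473 to 18337624 per library, which is a common scale set by the transformation and no count of reads. Of the symbols, 45217 (95.0%) had a single position in GENCODE release M21, which is on GRCm38, and coordinates are from that annotation, 1-based.

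A quasi-likelihood count test had been chosen before the data were examined, together with its filter, the gene lists, the rule for named genes and most alternatives. It needs counts, so the values were tested as they stand with limma 3.58.1 in R 4.3.3, with the trend and robust options. The plan for normalized values added a pseudocount of 1 before taking logarithms. That step was left out because the values were already logarithms. A gene was tested when its value reached the log2 of 10 in at least 3 libraries, which left 15055 genes. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors given with a log2 fold change are the moderated standard errors (SE) of limma, and errors given with a level are standard deviations (SD) over the 3 samples of a group. Linear folds are 2 to the power of the log2 fold change. Tables were prepared and figures drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

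The 31 gene lists were written from general knowledge of the pathways and cell types, without use of these samples. They were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 31 lists, and again with an estimated correlation and with fry. With an estimated correlation, camera also works with the residual degrees of freedom of the libraries instead of the number of genes. A call can thus be lost there without correlated members. Members of each list were also counted with the adjustment made over the list alone. The genes named in the text follow a rule. It takes the 12 highest and 12 lowest log2 fold changes among called genes whose 3 + 3 libraries did not overlap and whose mean CPM was at least 1, computed here as the share of the summed 2^value. It adds up to 4 members per list with the smallest p, and 14 genes whatever their values (Apoe, Gpnmb, Cdkn1a, Cdkn2a, Trp53, Glb1, Lmnb1, Syp, Syn1, Dlg4, Snap25, Map2, Tubb3 and Rbfox3). Some genes that the rule takes are not reported here. Genes named outside the rule are marked as chosen after their values were seen. Near-identical paralogs, such as Ifit3 and Ifit3b, Gbp genes and H2 genes, are uncertain, because the counting could divide reads among them, and genes that overlap another gene on either strand are uncertain for the same reason.

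The procedure was tested on simulated data, with 200 of the 15055 genes changed at the levels and spreads of the deposited values. It recovered 32.0% of the genes changed by 0.10 on the log2 scale and 100% of those changed by 0.20, 0.50 or 1.00. It made 4 false calls, 2.35% of its calls, and called the single list raised on purpose and 0 of the 30 others. The simulated genes were drawn independently, whereas estimated correlations within lists reached 0.96 in the data. The list result therefore does not cover lists with correlated members. The simulation also changed far fewer genes than the 3742 called in the data, so its rates may not carry over. Its changes were added on the deposited scale, with the shrunken spread of that scale. A true change of a weakly expressed gene is smaller on that scale, so these rates do not give the recovery of true changes. The alternatives covered other filters, thresholds, scalings and limma options, each library left out in turn, a block for the replicate number, and a correction for gene length and GC content. Alternatives that need counts were not run.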

Results

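Gene expression was compared between mouse primary hippocampal neurons treated for 24 h with 6 µg/mL of microglial apoE particles and neurons treated with the same dose of astrocytic apoE particles (n = 3 samples per group). ApoE is the main lipid carrier of the brain, and astrocytes and microglia both release it. The comparison asked how the cellular origin of the particles alters the neuronal transcriptome, with senescence and synaptic genes as the stated interest of the series. Values were deposited on a log2 scale common to the libraries, with a sum of 2^value of 18060473 to 18337624 per library, and the sequencing depth behind them is unknown. The median absolute log2 difference between libraries was 0.026 to 0.037 within a group and 0.043 to 0.056 between groups.

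The interferon-induced genes Oasl2 and Ifit1 rose 9.91-fold and 5.95-fold with microglial apoE. Smaller rises were found for Slc7a11, Hmox1 and Igfbp3, of the oxidative stress and secretory lists, and for Cdkn1a and Trp53, of the p53 list. The astrocyte gene Gfap and the cell division genes Top2a and Mki67 fell. Of 15055 genes tested, 3742 (24.9%) changed in limma, 1962 of them higher and 1780 lower with microglial apoE (adjusted p under 0.05). Most changes were small: 3126 of the changed genes (83.5%) differed by less than 0.20 on the log2 scale, and the median size was 0.12. A difference of at least 1.00 was reached by 33 genes, 32 of them higher, and the single lower gene was Gfap. The median SE of a log2 fold change was 0.029, with a range of 0.014 to 0.035 from the 5th to the 95th percentile. The transformation of the deposited values shrinks the SDs and SEs of weakly expressed genes together with their fold changes. At values of 4 to 12, where most tested genes lie, the median SD was below that of counting if 2^value were a count. SEs and p-values of such genes may therefore be too small.

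The share of higher calls moved with the scaling. It was 52.4% as deposited, 34.8% (1478 higher and 2765 lower) after centring each library on its median, and 65.6% (2516 higher and 1318 lower) with the sum of 2^value made equal. With mitochondrially encoded genes left out and the sum over the rest made equal as well, it was 41.7% (1668 higher and 2330 lower).

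The highest log2 fold change belonged to Oasl2, an interferon-induced member of the oligoadenylate synthetase family (protein-coding, GRCm38 chromosome 5, 114896936 to 114912234). Its level was 8.63 ± 0.03 with astrocytic and 11.93 ± 0.04 with microglial apoE (log2, SD, n = 3), a 9.91-fold difference (log2 fold change 3.31 ± 0.030 SE, limma adjusted p = 6.2e-30). Ifit1, which binds viral RNA (chromosome 19, 34640871 to 34650009), rose 5.95-fold, from 8.22 ± 0.02 to 10.79 ± 0.02 (adjusted p = 8.8e-28). Others among the 12 highest were Ifit3 (2.51), Iigp1 (2.27), Bst2 (2.06), Isg15 (2.03), Usp18 (2.01), Rnf213 (2.002), Ifi44 (1.99), Rsad2 (1.64) and Rtp4 (1.60), with log2 fold changes in parentheses and SEs of 0.030 to 0.040. The counting could divide reads between Ifit3 and Ifit3b, so Ifit3 is uncertain.

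All 32 tested members of the interferon response list of 34 rose, over all genes tested and adjusted over the list alone, with a median log2 fold change of 1.30. The call (camera adjusted p = 7.7e-74) held with an estimated correlation (adjusted p = 0.016). The list holds antiviral effectors such as Rsad2, the ubiquitin-like modifier Isg15 and its protease Usp18, and Bst2, which tethers budding viruses. Markers of microglia and macrophages, the cells that made the particles, stayed low in the same libraries: the 23 markers with any signal summed to 930.5 on the 2^value scale with microglial apoE and to 899.9 with astrocytic apoE.

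**Figure D1:**
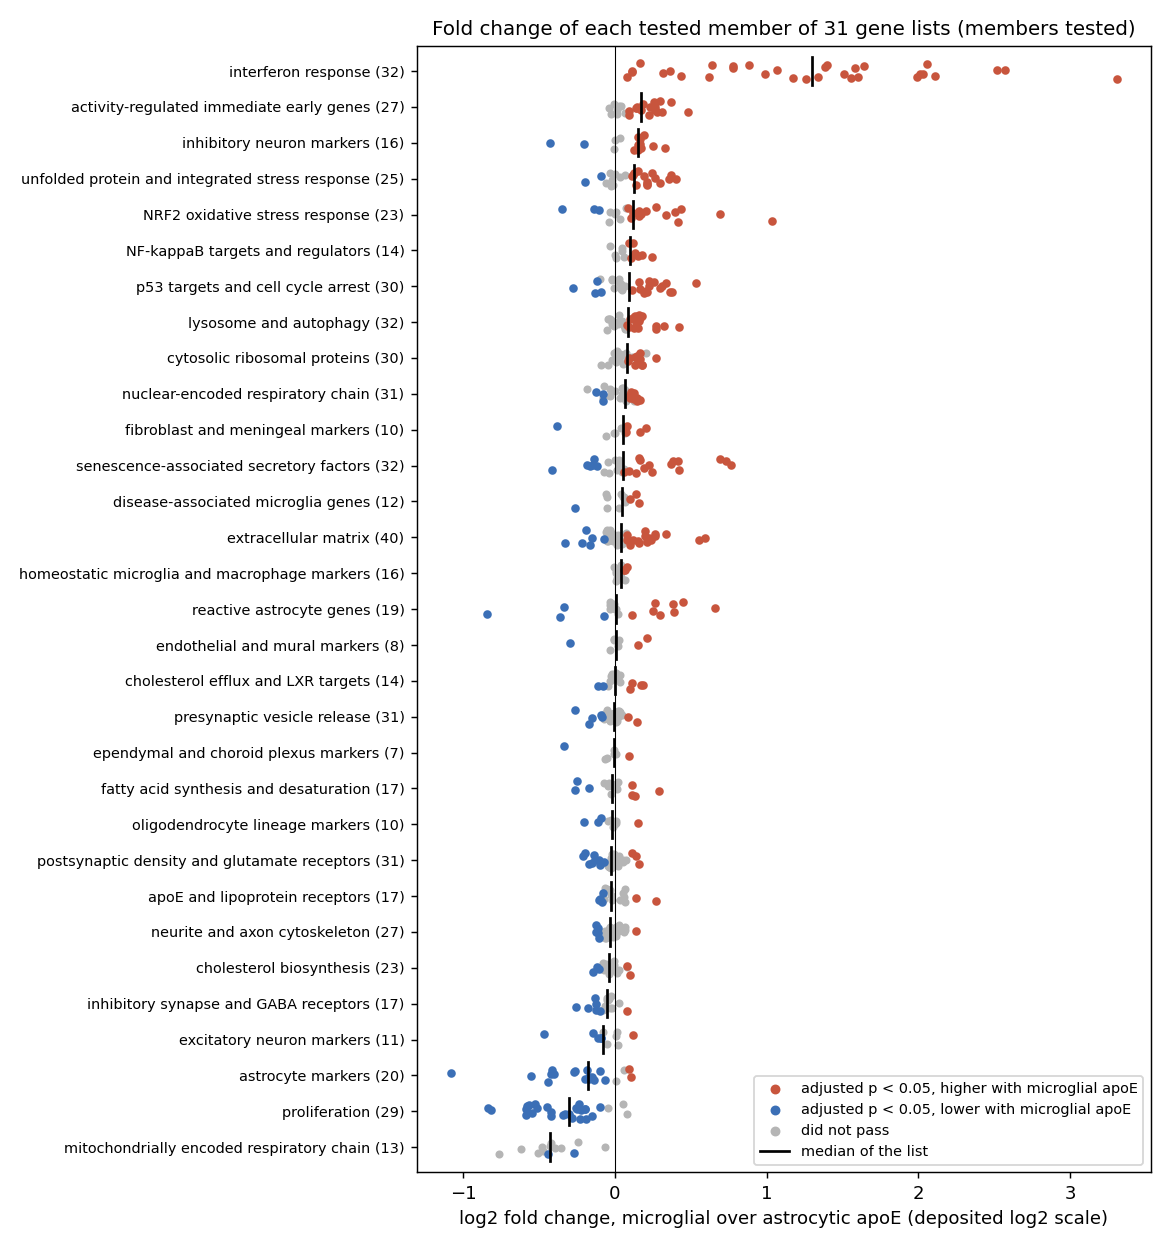
Log2 fold change (microglial against astrocytic apoE, n = 3 per group) of each tested member of the 31 gene lists, 1 point per gene. Red and blue points passed the test as higher and lower, grey points did not pass, and the black mark is the list median, which is 1.30 for the interferon response and -0.30 for proliferation.

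Of 23 tested genes of the NRF2 oxidative stress response, 14 rose with microglial apoE and 3 fell, and 15 rose and 3 fell adjusted over the list alone (median 0.12, camera adjusted p = 2.8e-06). The call was lost at adjusted p = 0.20 with an estimated correlation. Slc7a11, the cystine transporter that feeds glutathione synthesis, rose 2.05-fold, from 11.31 ± 0.04 to 12.34 ± 0.08 (SD, n = 3, adjusted p = 7.6e-17). Hmox1, which degrades haem, rose 1.61-fold (log2 fold change 0.69 ± 0.027 SE), and the thioredoxin reductase Txnrd1 rose 1.34-fold (0.42 ± 0.026 SE). The 3 that fell, named after their values were seen, were the metallothioneins Mt1 (-0.35) and Mt2 (-0.14) and the glutathione transferase Gsta4 (-0.11). In the unfolded protein and integrated stress response list, 15 of 25 genes rose and 2 fell, with the same counts adjusted over the list alone (median 0.12, camera adjusted p = 2.8e-06, adjusted p = 0.20 with an estimated correlation). Its leading members were the amino acid transporter subunits Slc3a2 (0.40) and Slc7a5 (0.30), the pseudokinase Trib3 (0.37) and the transcription factor Atf3 (0.36). The 2 that fell, also named afterwards, were the endoplasmic reticulum chaperones Pdia4 (-0.20) and Hsp90b1 (-0.09).

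Of 30 tested genes tied to p53 and cell cycle arrest, 15 rose with microglial apoE and 4 fell, and 16 rose and 5 fell adjusted over the list alone (median 0.091, camera adjusted p = 3.4e-06). The call held with an estimated correlation (adjusted p = 0.040). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 17, 29090976 to 29100727), rose 1.30-fold, from 11.13 ± 0.04 to 11.51 ± 0.01 (SD, n = 3, adjusted p = 6.9e-11). Trp53 itself (chromosome 11, 69580359 to 69591873) rose 1.26-fold (log2 fold change 0.33 ± 0.028 SE, adjusted p = 7.6e-10). Gadd45a, a DNA damage response gene, rose by 0.54 ± 0.031 SE on the log2 scale and the stress-responsive Sesn2 by 0.30 ± 0.026 SE. The 4 that fell were the cell cycle inhibitor Cdkn2c (-0.28), the stress gene Sesn1 (-0.13), the nuclear lamin Lmnb1 (-0.12 ± 0.031 SE, adjusted p = 0.0068) and the death receptor Fas (-0.09), all but Lmnb1 named after their values were seen. Cdkn2a, which encodes p16 and ARF, did not pass (0.03 ± 0.014 SE, adjusted p = 0.15), nor did Glb1, the gene of senescence-associated beta-galactosidase (-0.01 ± 0.031 SE, adjusted p = 0.90). With the sum of 2^value made equal, Cdkn2a passed (adjusted p = 0.034). Its level was low, 4.05 ± 0.01 with astrocytic and 4.08 ± 0.02 with microglial apoE (SD, n = 3). The transformation shrinks fold changes at such levels, so these values cannot show that Cdkn2a was unchanged.

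Among 32 tested secretory factors linked to senescence, of 47 listed, 15 rose and 6 fell, and 20 rose and 7 fell adjusted over the list alone (median 0.051, camera adjusted p = 4.3e-05). The call was lost at adjusted p = 0.20 with an estimated correlation, and the median was 0.14 at the filter of 50 on the 2^value scale (25 tested), 0.028 with no filter on low values (45 tested) and 0.033 with median centring. Gdf15, a stress-induced cytokine, rose 1.70-fold, and Igfbp3, an insulin-like growth factor binding protein, rose 1.66-fold, from 12.25 ± 0.03 to 12.99 ± 0.04 (SD, n = 3). Csf1 (0.42 ± 0.028 SE), a growth factor of microglia, and the protease inhibitor Serpine2 (0.41 ± 0.027 SE) rose less. Igfbp5, named after its value was seen, fell by 0.41 on the log2 scale. Of 32 lysosome and autophagy genes, 17 rose and 0 fell (18 and 0 adjusted over the list alone, median 0.085, camera adjusted p = 2.4e-06, adjusted p = 0.23 with an estimated correlation). The autophagy receptor Sqstm1 rose 1.34-fold (0.42 ± 0.027 SE), the proteases Ctsl and Ctsd by 0.32 ± 0.031 and 0.27 ± 0.026 SE, and progranulin (Grn) by 0.27 ± 0.031 SE.

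Of 27 immediate early genes, which neuronal activity and growth factors induce, 19 rose with microglial apoE and 0 fell, the same adjusted over the list alone (median 0.17, camera adjusted p = 2.3e-11, adjusted p = 0.14 with an estimated correlation). Nr4a1 rose 1.40-fold (0.48 ± 0.031 SE), and Cyr61 (0.37 ± 0.030 SE), Egr1 (0.31 ± 0.032 SE) and Fosb (0.30 ± 0.029 SE) rose less. Of 14 NF-kappaB genes, 8 rose and 0 fell, the same adjusted over the list alone (median 0.10, camera adjusted p = 6.8e-04, adjusted p = 0.23 with an estimated correlation). They included the adhesion molecule Vcam1 (0.24 ± 0.026 SE) and the NF-kappaB subunit gene Nfkb2 (0.13 ± 0.031 SE), and the list median was 0.062 with no filter on low values. In the extracellular matrix list 17 of 40 genes rose and 6 fell (19 and 6 adjusted over the list alone, median 0.039, camera adjusted p = 0.013, adjusted p = 0.40 with an estimated correlation). That median was 0.063 at the filter of 50, 0.024 with no filter, 0.020 with median centring and 0.017 with the length and GC trend removed. Tenascin C (Tnc, 0.59 ± 0.030 SE) and fibronectin (Fn1, 0.56 ± 0.030 SE) rose 1.51-fold and 1.47-fold, and the astrocyte-enriched matrix gene Sparcl1 fell by 0.33 on the log2 scale.

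**Figure D2:**
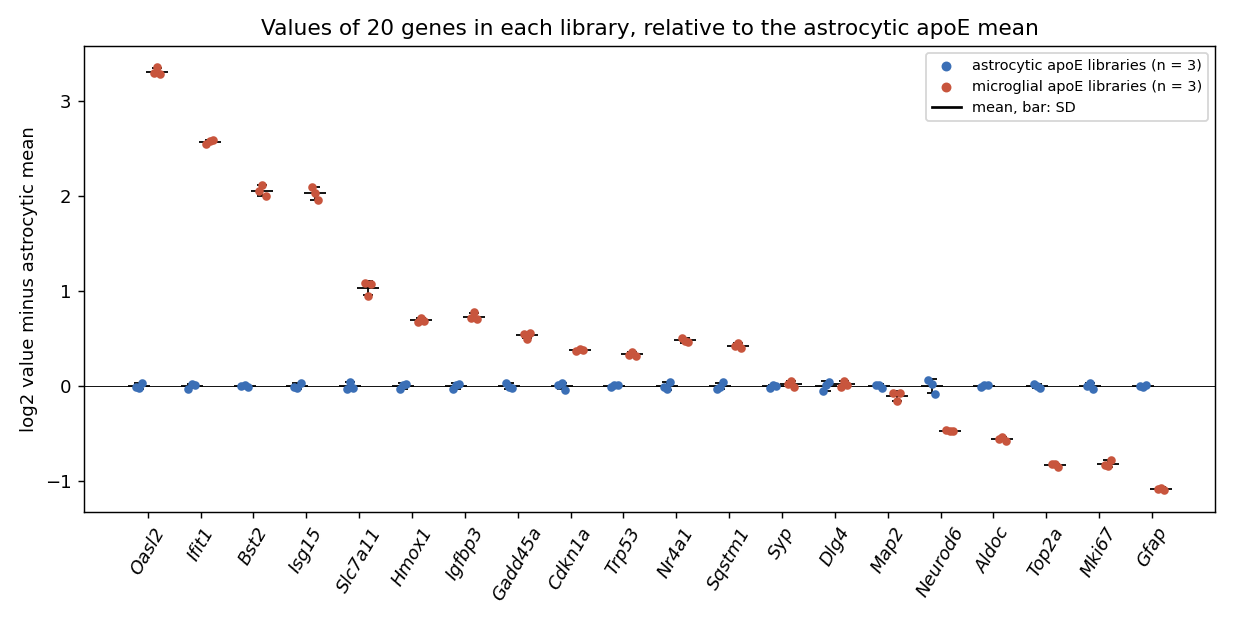
Level of 20 genes in each library as the log2 value minus the mean of the astrocytic apoE group, with the mean and SD of each group (n = 3). The interferon genes Oasl2, Ifit1, Bst2 and Isg15 lie above the astrocytic mean by 3.31, 2.57, 2.06 and 2.03, and Gfap lies 1.08 below it (log2 fold change -1.08).

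Synaptic genes changed in both directions and by little. Of 31 presynaptic vesicle genes 2 rose and 5 fell, the same adjusted over the list alone (median -0.0040, camera adjusted p = 0.29). Sv2b, a synaptic vesicle glycoprotein, fell by 0.27 on the log2 scale (SE 0.032), and Syt4, a synaptotagmin, fell by 0.15 (SE 0.028). Of 31 postsynaptic genes 3 rose and 9 fell, and 4 rose and 9 fell adjusted over the list alone (median -0.025, camera adjusted p = 0.18). That median was -0.0052 without microglial replicate 2 and -0.0081 without astrocytic replicate 3. The scaffold gene Homer2 (-0.21 ± 0.036 SE), the adhesion gene Lrrtm2 (-0.20 ± 0.031 SE) and the metabotropic glutamate receptor Grm5 (-0.17 ± 0.031 SE) fell, and the AMPA receptor subunit Gria3 rose (0.16 ± 0.027 SE). The general markers Syp (0.02 ± 0.026 SE, adjusted p = 0.60), Syn1 (-0.03 ± 0.029 SE, adjusted p = 0.56), Snap25 (-0.01 ± 0.028 SE, adjusted p = 0.77) and Dlg4 (0.02 ± 0.029 SE, adjusted p = 0.65) did not pass.

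In the list of inhibitory synapse and GABA receptor genes 1 of 17 rose and 6 fell, and 1 rose and 7 fell adjusted over the list alone (median -0.053, camera adjusted p = 0.0022). The call was lost at adjusted p = 0.38 with an estimated correlation. The receptor subunits Gabrg1 (-0.26 ± 0.033 SE) and Gabra5 (-0.18 ± 0.028 SE) fell, and the member that rose, named afterwards, was the chloride transporter Slc12a5 (0.08). Of 27 neurite and axon cytoskeleton genes 1 rose and 5 fell, the same adjusted over the list alone (median -0.034, camera adjusted p = 0.10). That list passed without astrocytic replicate 1 (adjusted p = 0.042), with no filter on low values (adjusted p = 0.026) and with the length and GC trend removed (adjusted p = 0.031), and its median was -0.012 without microglial replicate 2 and -0.014 without astrocytic replicate 3. The axon growth gene Stmn2 (-0.13 ± 0.025 SE) and the neurofilament Nefl (-0.12 ± 0.028 SE) fell, and the neuronal tubulin Tubb3 did not pass (0.03 ± 0.027 SE, adjusted p = 0.47). The dendritic protein gene Map2 fell (-0.10 ± 0.027 SE, adjusted p = 0.0055), a call lost without astrocytic replicate 2 (adjusted p = 0.051). Rbfox3, which encodes the neuronal nuclear antigen NeuN, fell by 0.08 on the log2 scale (SE 0.027, adjusted p = 0.038), and this call was lost without any 1 of the 6 libraries (adjusted p = 0.052 to 0.13), with no filter on low values (adjusted p = 0.077) and with the sum of 2^value made equal (adjusted p = 0.096).

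Among excitatory neuron markers 1 of 11 rose and 5 fell (1 and 6 adjusted over the list alone, median -0.079, camera adjusted p = 0.031, adjusted p = 0.20 with an estimated correlation). The call was also lost without astrocytic replicate 3 (adjusted p = 0.089) and with median centring (adjusted p = 0.053). Neurod6, a transcription factor of pyramidal neurons, fell by 0.47 on the log2 scale, from 12.49 ± 0.07 to 12.02 ± 0.01 (SD, n = 3), and Bcl11b rose by 0.12. Among inhibitory neuron markers 11 of 16 rose and 2 fell, the same adjusted over the list alone (median 0.15, camera adjusted p = 6.8e-04, adjusted p = 0.15 with an estimated correlation). Sst, the somatostatin gene, rose by 0.33 ± 0.031 SE and Gad1, which makes GABA, by 0.25 ± 0.025 SE, whereas Cck (-0.43 ± 0.031 SE) and Pvalb (-0.20 ± 0.020 SE) fell.

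Astrocyte transcripts were detected in the cultures, and of 20 tested astrocyte markers 16 fell with microglial apoE and 2 rose (median -0.18, camera adjusted p = 9.3e-12). Adjusted over the list alone, 16 fell and 3 rose, and the call held with an estimated correlation (adjusted p = 0.024). Gfap, the intermediate filament of astrocytes (chromosome 11, 102887336 to 102900912), stood between 12.99 and 13.01 in the 3 astrocytic apoE libraries and at 11.92 ± 0.02 with microglial apoE (SD, n = 3), 2.12-fold lower (log2 fold change -1.08 ± 0.026 SE, adjusted p = 2.7e-21). The glycolytic enzyme Aldoc (-0.56 ± 0.026 SE), the gap junction gene Gja1 (-0.44 ± 0.028 SE) and the lipid binding protein Fabp7 (-0.40 ± 0.026 SE) fell. The 2 that rose, named afterwards, were the glutamate transporter Slc1a3 (0.09) and the coagulation factor receptor F3 (0.10). Genes of reactive astrocytes went both ways: 8 of 19 rose and 4 fell, the same adjusted over the list alone (median 0.010, camera adjusted p = 0.10), and with no filter on low values the list passed (adjusted p = 0.043). Lcn2 (0.66 ± 0.030 SE), complement C3 (0.45 ± 0.029 SE) and ceruloplasmin (Cp, 0.39 ± 0.027 SE) rose, whereas Serpina3n fell by 0.84 on the log2 scale (SE 0.027). A2m, an extracellular protease inhibitor, fell by 0.86 (SE 0.027).

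Of 29 tested proliferation genes 26 fell and 0 rose with microglial apoE, in the same libraries in which the astrocyte markers had a median of -0.18, and 26 fell and 1 rose adjusted over the list alone (median -0.30, camera adjusted p = 3.0e-29). The call held with an estimated correlation (adjusted p = 0.0063). Top2a, the topoisomerase of dividing cells (chromosome 11, 98992943 to 99024189), fell by 0.83 on the log2 scale, from 9.63 ± 0.02 to 8.80 ± 0.02 (SD, n = 3), and Mki67, the antigen Ki-67, fell by 0.82. The cyclins Ccnb1 (-0.59 ± 0.032 SE) and Ccna2 (-0.58 ± 0.030 SE), the mitotic motor Kif11 (-0.58 ± 0.032 SE) and the kinetochore gene Cenpf (-0.56 ± 0.029 SE) were also among the 12 lowest. The remaining 3 of those 12 were Net1 (-0.70 ± 0.032 SE), the mitochondrial glutamate carrier Slc25a18 (-0.63 ± 0.030 SE) and Fam107a (-0.58 ± 0.034 SE).

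Of 16 tested markers of homeostatic microglia and macrophages 3 rose and 0 fell, the same adjusted over the list alone (median 0.039, camera adjusted p = 0.027, adjusted p = 0.20 with an estimated correlation). That call was also lost without astrocytic replicate 3 (adjusted p = 0.094), at the filter of 50 on the 2^value scale (adjusted p = 0.15), with median centring (adjusted p = 0.085), with mitochondrially encoded genes left out and the sum over the rest made equal (adjusted p = 0.054) and with the length and GC trend removed (adjusted p = 0.076), and the median was 0.019 with no filter on low values and 0.020 with median centring. The lysosomal protease Ctss was the marker with the smallest p (0.06 ± 0.016 SE). Of 12 disease-associated microglia genes 3 rose and 1 fell (6 and 2 adjusted over the list alone, median 0.046, camera adjusted p = 0.30). Fabp5 fell by 0.26 on the log2 scale, Ctsz rose by 0.16, and Gpnmb did not pass (0.05 ± 0.022 SE, adjusted p = 0.099) except with the sum of 2^value made equal (adjusted p = 0.042). Oligodendrocyte lineage markers (10 tested, 1 higher and 3 lower, median -0.020, camera adjusted p = 0.20), fibroblast and meningeal markers (10 tested, 4 higher and 1 lower, median 0.053, camera adjusted p = 0.22) and endothelial and mural markers (8 tested, 2 higher and 1 lower, median 0.0085, camera adjusted p = 0.53) did not pass in camera, with the same counts adjusted over the list alone. Of 7 ependymal and choroid plexus markers 1 rose and 1 fell, and 1 rose and 2 fell adjusted over the list alone (median -0.0073, camera adjusted p = 0.20). In fry, which tests a list without comparing it with other genes, the oligodendrocyte lineage (adjusted p = 0.017) and ependymal and choroid plexus lists (adjusted p = 0.0014) passed as lower. Pdgfra, a gene of fibroblasts and of oligodendrocyte precursors, fell by 0.38 (SE 0.030), and Ttr, the transthyretin gene of the choroid plexus, by 0.33 (SE 0.020).

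None of the 4 lists of lipid handling genes passed in camera. Apoe stood at 15.10 ± 0.04 with astrocytic and 15.10 ± 0.03 with microglial apoE (SD, n = 3, log2 fold change 0.00 ± 0.026 SE, adjusted p = 0.93). Of 23 cholesterol biosynthesis genes 2 rose and 3 fell (median -0.040, camera adjusted p = 0.13), and of 14 cholesterol efflux and LXR target genes 4 rose and 2 fell (median 0.0029, camera adjusted p = 0.42), with the same counts adjusted over each list alone. Dhcr7, the last enzyme of cholesterol synthesis, fell by 0.15 (SE 0.033), and the cholesterol exporter Abca1 (0.12 ± 0.027 SE) and Apod (0.18 ± 0.022 SE) rose. Of 17 fatty acid genes 4 rose and 3 fell, and 4 rose and 4 fell adjusted over the list alone (median -0.019, camera adjusted p = 0.47), with the desaturase Fads2 lower (-0.26 ± 0.025 SE) and Fads3 higher (0.29 ± 0.028 SE). Of 17 apoE and lipoprotein receptor genes 2 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.73), and the list's median (-0.028) and mean (0.0036) differed in sign. The receptor genes Lrp2 (0.27 ± 0.032 SE) and Vldlr (0.14 ± 0.029 SE) rose, and Lrp8 fell by 0.10 (SE 0.027).

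Transcripts encoded by the mitochondrial genome took a smaller part of the libraries with microglial apoE. Their share of the summed 2^value was 7.92, 7.47 and 6.46% in the astrocytic apoE libraries (7.28% ± 0.745, SD, n = 3) and 5.71, 5.77 and 5.74% in the microglial apoE libraries (5.74% ± 0.030, SD, n = 3). The groups did not overlap, and an exact permutation test of 3 against 3, two-sided, cannot give a p under 0.1. Of 13 mitochondrially encoded respiratory chain genes 2 fell over all genes tested and 13 fell adjusted over the list alone (median -0.43, camera adjusted p = 9.2e-11, adjusted p = 0.25 with an estimated correlation). The 2 were mt-Nd1 (-0.44 ± 0.085 SE, adjusted p = 0.025) and mt-Co1 (-0.27 ± 0.063 SE, adjusted p = 0.033). The mt-Nd1 call was lost without astrocytic replicate 2 (adjusted p = 0.052) and without microglial replicate 1, 2 or 3 (adjusted p = 0.065, 0.084 and 0.064), and the mt-Co1 call without microglial replicate 2 (adjusted p = 0.16) and with no filter on low values (adjusted p = 0.092). Quantile normalization gives every library the same ranked values, which limits differences among the most abundant genes. Both calls were lost there, with a list median of -0.26.

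**Figure D3:**
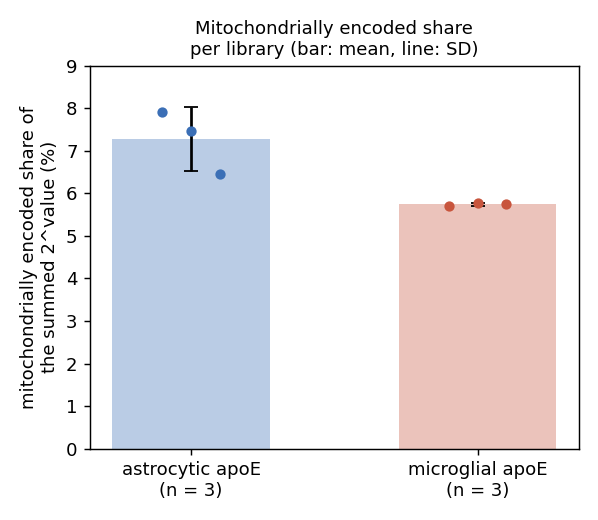
Share of the summed 2^value taken by mitochondrially encoded genes in each library, in percent, with points for libraries, bars for group means starting at 0 and lines for the SD (n = 3). The microglial apoE libraries lie between 5.71 and 5.77% and the astrocytic apoE libraries between 6.46 and 7.92%.

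Of 31 nuclear-encoded genes of the respiratory chain 9 rose and 3 fell, and 10 rose and 4 fell adjusted over the list alone (median 0.065, camera adjusted p = 0.027, adjusted p = 0.53 with an estimated correlation). This call was lost without astrocytic replicate 1 or 2 (adjusted p = 0.063 and 0.061), without microglial replicate 2 (adjusted p = 0.19), in fry (adjusted p = 0.14) and with the sum of 2^value made equal (adjusted p = 0.052). Cox5b (0.17 ± 0.034 SE) and Uqcrq (0.14 ± 0.029 SE), subunits of complexes IV and III, rose. Of 30 cytosolic ribosomal protein genes 12 rose and 0 fell, and 14 rose and 0 fell adjusted over the list alone (median 0.078, camera adjusted p = 1.7e-04). That call was lost at adjusted p = 0.46 with an estimated correlation and in fry (adjusted p = 0.11), and the median was 0.044 without microglial replicate 2 and 0.052 without astrocytic replicate 1. Rpl3 (0.16 ± 0.028 SE) and Rps19 (0.17 ± 0.030 SE) were among the members that rose. Over the 31 lists, 18 were called with the preset correlation, 13 higher and 5 lower, and 4 with an estimated correlation (interferon response, p53, astrocyte markers and proliferation). The medians of all 13 lists not called moved by over 1.5 times in at least 1 of the other settings run, and 6 of them changed sign. Of the 18 lists called, 6 moved by over 1.5 times and 0 changed sign. A median close to 0 moves that far with a small shift.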

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

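The scaling, limma option, treat and length and GC alternatives were chosen after the data were seen. With limma, leaving out 1 library gave 2556 (without astrocytic replicate 2) to 4541 (without astrocytic replicate 3) changed genes against 3742. Of the values for named genes under these settings, 2525 kept their side of the threshold, 279 lost it and 28 gained it, and 121 and 87 of the losses came from the size threshold and from treat. Adding an absolute log2 fold change of at least 1 left 33 genes, 32 higher and 1 lower. An adjusted p under 0.01 left 2335, 1253 higher and 1082 lower. Testing against a fold of 1.2 with treat left 170, 119 higher and 51 lower. These follow from stricter thresholds on mostly small changes. Median centring raised the lower calls from 1780 to 2765, since it lowers every fold by the same amount (the median of all genes went from -0.00057 to -0.019) and most changes are small. Among lists, 460 values kept their side, 27 lost it and 6 gained it. An estimated correlation left 4 lists of 18, 2 higher and 2 lower, and calls ended also where the estimate lay under the preset 0.01 (excitatory neuron markers, -0.0093, and homeostatic microglia, -0.0039). For p53, with an estimate of -0.021, the adjusted p in camera rose from 3.4e-06 to 0.040. Where the estimate lay under the preset, the smaller degrees of freedom, not correlated members, lie behind the higher p. The numbers of the samples gave no sign of pairing: the correlations of deviations for the same number were 0.039, -0.12 and -0.19. No astrocytic sample correlated best with its own number, and among microglial samples only replicate 1 did (0.039). With 3 samples per group these correlations cannot exclude a pairing, and the labels do not settle it. A replicate block gave 3387 genes and 18 lists. Not run, since they need counts, were the other count scalings (relative log, upper quartile, library size alone), the other count tests, voom and the planned count version of treat. Depth is unknown, so its limit cannot be given per gene. In the simulation, which changed far fewer genes than were called in the data, 32.0% of changes of 0.10 (log2) were recovered. Those changes were set on the deposited scale after shrinkage, so this rate does not stand in for a limit from depth.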

Other observations

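Families defined after the data were seen were also counted, with no test of enrichment. All 13 tested interferon-inducible GTPases, which act against intracellular pathogens, were higher with microglial apoE (median log2 fold change 0.83), among them Irgm1 (1.21) and Igtp (1.07). Of 22 genes of major histocompatibility complex class I and antigen processing, 18 were higher and 0 lower (median 0.31), with Tapbp at 0.75 and the immunoproteasome activator Psme2 at 0.43. Of 41 tripartite motif (TRIM) genes 19 were higher and 2 lower, led by Trim30a (1.42), Trim21 (0.92) and Trim30d (0.85), and of 12 poly(ADP-ribose) polymerase family genes 7 were higher and 1 lower, led by Parp12 (0.98), Parp14 (0.90) and Parp9 (0.88). Several GTPase and class I genes are also in the interferon list, and near-identical Gbp, Trim30 and H2 genes are uncertain. Of 18 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and include targets of the transcription factor ATF4, 15 were higher and 0 lower (median 0.15), with Wars, also induced by interferon, highest at 0.37. Both mitochondrially encoded ribosomal RNAs were lower (2 of 2, median -0.23). These counts are of limma calls over all genes.

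The tests of microglial RNA and of a uniform fall of astrocyte markers were chosen after their results were seen, those of the scaling without mitochondrially encoded genes and of the length and GC trend were added after the data were seen but before their own results, and the count of splits was planned. Only 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many changed genes: 3742 in limma against at most 0 in another split (100 to 804 genes there at an unadjusted p under 0.05). Likewise 1 of 10 gave as many lists, 18 against at most 15. With 10 splits the share cannot fall under 0.05. Other splits still set libraries of both treatments unevenly against each other, so part of the treatment difference stays in them. They also mix both treatments within each group, which widens the spread there, so 0 genes in them is no evidence against a chance split. Those splits with 0 genes still called 4 to 15 lists.

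The first pattern is the rise of interferon genes. Microglial RNA carried over in the proportions of whole microglia would bring the abundant microglial transcripts, yet the whole level of 23 microglial and macrophage markers in the microglial apoE libraries was 0.041 of the summed rise of the 32 interferon genes (930.5 against 22698 on the 2^value scale). Particle RNA of another composition need not bring these markers, so it was not tested here. Of these markers 16 passed the level filter, and Oasl2 alone rose by 3520.2. A scaling shift from mitochondrially encoded transcripts would move all genes alike, yet the median of all genes was -0.00057 against 1.30 for the list, and leaving these transcripts out with the sum over the rest made equal moved every gene by the same small amount, so that the share of 0.992 of the list median kept adds nothing to this. A response of the cells in the culture to the microglial particles, or to interferons or other factors carried with them, may explain the rise. It stays a hypothesis and was not tested, and which cells of the culture responded is open. Lower interferon genes with astrocytic apoE would give the same difference. The 2 cannot be separated, since untreated neurons were not analysed here.

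The second pattern is the fall of astrocyte markers beside that of cell division genes. A lower share of astrocytes alone would lower the markers by a common factor if no other cells of the culture expressed them. A share of 0.6 of the 20 markers lay more than 3 SE from their median. Of the 7 with a mean value of at least 12, where the median SD of all genes (0.0312) is not below that of counting (0.0181, if 2^value were a count), 5 lay so far from their own median, with Gfap at -1.08 and Slc1a3 at 0.09. Expression of these markers in other cells was not measured, so their unequal fall cannot decide on a lower share of astrocytes. A length and GC trend is argued against, since the median kept 1.01 of its value with that trend removed. A change of state in astrocytes of the culture, fewer of them, or both may account for the fall and was not tested apart from these values. An effect of astrocytic apoE in the opposite direction cannot be separated, since untreated neurons were not analysed here.

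The third pattern is lower GABA receptor genes, which have long transcripts, with higher ribosomal protein genes, which have short ones. A trend with transcript length or GC content could produce this, and across genes the log2 fold change had a Spearman rho of -0.018 with length and 0.20 with GC content (genes are not independent replicates). With both trends removed per library, the GABA receptor list kept 0.948 and the ribosomal list 0.929 of its median, which argues against such a trend as the whole cause. Both lists lose their call with an estimated correlation (adjusted p = 0.38 and 0.46), so whether they differ from other genes stays open. The ribosomal median of 0.078 was 0.044 without microglial replicate 2 and 0.052 without astrocytic replicate 1. The extracellular matrix list, outside this pattern, kept less of its median, which went from 0.039 to 0.017 with both trends removed. A length or GC trend is therefore not argued against for every called list.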
